A study of Caenorhabditis elegans with 2 samples.

How the data were processed

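Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the transcription factor PHA-4 was measured in whole L4 larvae of Caenorhabditis elegans strain OP37, which carries an eGFP-tagged pha-4 insertion in an unc-119 mutant background. The labels give 1 group with 2 biological replicates of mixed sex and name PHA-4 as the antibody target, while their description calls the target eGFP-tagged PHA-4. Library fragments ranged from 150 to 350 bp per the labels. The 2 replicates are separate biological samples per the labels, and nothing further is said of how the cultures were grown. The protocol of extraction was not given in the sources used here.

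The deposited files were lists of regions in narrowPeak layout for the genome builds ce10 and ce11. Per the manifests deposited with them, each replicate's list was called on that replicate's alignments against a control, and the pooled list on both replicates' alignments against a control. These lists keep background regions on purpose, as input for the irreproducible discovery rate (IDR) procedure, which keeps regions that rank alike in the replicates. The IDR-thresholded list was derived from the pooled list and both replicates' lists, per the manifests. The peak caller, its version and the IDR threshold were not given in the sources used here. The signal of each region is the value the authors deposited in the seventh column, and its scale is not stated. The authors deposited a −log10 q value for each region, which is capped, so regions were ranked by signal. The deposited summit offset, in bp from the start of the region, gave the summit. The control's data were not analysed here, and the files give no read counts, so the depth of each library is unknown and no interval that needs it was computed.

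Each IDR region had the coordinates and signal of a region in the pooled list, and the IDR list held that list's strongest 1484 regions on ce11 and strongest 1737 on ce10. A single region of the IDR list thus need not rank alike in both replicates. All coordinates below are on ce11, which has the sequence of the WBcel235 assembly. Genes came from Ensembl release 115 for that assembly. The ce10 lists were used only for counts within that build. No value came from columns of other samples.

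Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1. Replicates were compared by the share of replicate 1's strongest 1484 regions that overlapped replicate 2's strongest 1484 by at least 1 bp. Chance was estimated from 100 random placements of replicate 2's regions on the same chromosomes and from 100 random draws out of replicate 2's whole list. A replicate's signal at an IDR region was that of its strongest region with a summit within 150 bp.

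Each summit was placed in the first of 5 classes that applied. These were the promoter window of a protein-coding gene, from 1000 bp upstream to 200 bp downstream of any annotated transcript 5' end, the same window of a non-coding RNA gene, an exon, an intron, and intergenic sequence. Shares of summits were tested against the class's share of bases with a two-sided exact binomial test. A gene was tied to a region when the summit lay in its promoter window, so 1 region can count for several genes. Gene lists and gene classes (the letters before the hyphen of a gene name, with at least 15 members) were tested with Fisher's exact test, two-sided, against the other named protein-coding genes. The 19 lists covered pharynx, intestine, rectum and excretory system, somatic gonad, body wall muscle, epidermis, neurons, germline, autophagy and lysosome, antioxidant and stress response, and insulin, TOR and diet pathways. They also covered vacuolar ATPase, cytosolic ribosomal proteins, core histones, collagens, nuclear hormone receptors, homeobox genes, forkhead and GATA factors, and seven-transmembrane chemoreceptors. Lists written by hand are small and incomplete, and some genes stand in more than 1 list.

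Sequence windows reached 50 bp to each side of the summit and were compared with windows of the same width centred 500 bp away, to a side drawn at random with a fixed seed. The tests were exact two-sided binomial tests on the regions in which only 1 of the windows held the sequence. The PHA-4 consensus TRTTKRY (R is A or G, K is G or T, Y is C or T) and 5 comparison sequences were tested on either strand, as were all sequences of 7 bases. Chromosome shares were tested against shares of protein-coding promoter windows with a two-sided exact binomial test. P-values were adjusted by Benjamini and Hochberg within each family of tests, with a threshold of 0.05. Those introduced as exact p without the word adjusted are unadjusted. All p-values treat genes or regions as the units, so they do not measure the spread between replicates. Intervals are exact 95% binomial intervals and cover the counting of genes or regions alone. With 1 group, no contrast between conditions could be made.

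The tests were tried on simulated data. Lists planted at 4 times the background rate among 10896 genes were called in 97.3% of draws and at 3 times in 77% of draws, against 1.64% of unplanted lists. The planted lists had 40 to 156 genes, so these shares need not hold for lists of 21 or 25 genes. No list was planted below the background, and calls were drawn gene by gene, without regions shared between genes. Gene classes planted at a 50% rate were called in 100% of draws and unplanted ones in 0.0893%. With nothing planted, 0 motifs and 0 sequences of 7 bases were called among 1500 windows at random positions, and a planted sequence ranked 1. Random windows and their flanks were not set apart in base composition, whereas real summit windows held 44.2% G+C and flanks 35.6%. The simulation therefore does not cover calls that such a difference can cause. The overlap step returned 50.2% when 50% of 1000 regions were shared.

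The named genes followed a rule fixed before the data were examined, as were the lists, the tests and most alternatives. It took pha-4 and unc-119, the 12 protein-coding genes with the strongest IDR region in their window, up to 4 members with the strongest region and up to 2 alphabetically first members without one from each list. It also took the 3 strongest IDR regions outside every promoter window and up to 3 members of each gene class that passed the test. The alternatives were another overlap rule, other numbers of regions, the ce10 lists, a stricter signal threshold, other windows and gene rules, another background, a rotation of the calls along the gene order (1000 rotations), other motif definitions, sequence lengths and backgrounds, and each replicate alone. Added after the data were seen were the deeper pooled lists, the IDR list without a dense run of regions around pha-4, and chromosome shares of promoter regions only.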

Results

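PHA-4 is the FoxA transcription factor that specifies the pharynx, the feeding organ of the worm, and it also acts in the intestine, the somatic gonad, autophagy and the response to diet. Its binding was profiled by ChIP-seq in whole L4 larvae, the last larval stage, in 1 group of 2 biological replicates. The lists held 21039 regions for replicate 1, 20807 for replicate 2 and 30000 for both pooled, background regions included. The authors' IDR list held 1484 regions with a median width of 310 bp (78 to 399) and a median signal of 33.8 (25.9 to 226). Signal below is the authors' value for each region, from the pooled list unless a replicate is named. The design holds no second condition, so the questions are where the factor was found, how far the replicates shared those places, and which genes and sequences lay there.

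The replicates shared 744 of their strongest 1484 regions, which is 50.1% (exact 95% interval 47.6 to 52.7%). Random placement of replicate 2's regions gave a mean of 0.900% (0.472 to 1.55% in 100 placements), and random draws from replicate 2's whole list gave 7.36% (5.73 to 9.10%). The overlap was 31% among the strongest 100 regions, 45% among the strongest 500 and 57.3% among the strongest 6000, and fell to 54.2% among the strongest 10000 and 47.45% among the strongest 20000. Of the IDR regions, 1080 (72.8%) overlapped replicate 1's strongest 1484, 1065 (71.8%) overlapped replicate 2's, 730 (49.2%) overlapped both and 69 (4.65%) neither. The whole lists covered 99.7% of the IDR regions in each replicate. In 1459 IDR regions with a region in both replicates, the median log2 ratio of replicate 1 to replicate 2 was 0.16 with an SD of 0.83 across regions, and 290 regions (19.9%) differed by more than 2-fold. Across these regions, which are not independent replicates, Spearman's rho of the signals was 0.0690 and Pearson's r of the log2 signals was 0.0849. The IDR list holds the strongest regions by pooled signal, to which both replicates contribute. Such a cut narrows the range of both replicates and can by itself lower their correlation among the regions kept. Across 7769 regions of the whole pooled list matched in both replicates, rho was 0.522 and r was 0.544.

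**Figure D1:**
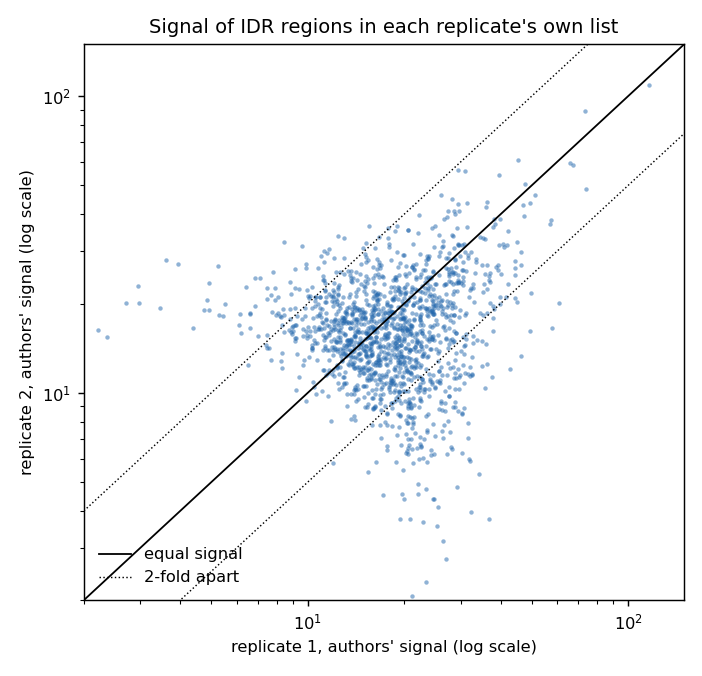
Signal of 1459 IDR regions in replicate 1 (x axis) and replicate 2 (y axis), each from the replicate's own list, both on log scales without a unit; the solid line marks equal signal and the dotted lines 2-fold differences. Most points form a round cloud, with 290 regions outside the dotted lines and the few strongest regions near the line of equal signal.

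The strongest region in a promoter window of a protein-coding gene, at II:10563480 to 10563642, had a signal of 127 (67.3 in replicate 1 and 58.7 in replicate 2) and its summit 155 bp upstream of cdc-48.1 (WBGene00007352), which encodes an AAA ATPase that extracts ubiquitinated proteins. A region of signal 107 at IV:4750003 to 4750171 (45.2 and 61.2) lay between rpl-20, a ribosomal protein gene, and Y17G9B.5. The region between eef-1G, a translation elongation factor gene, and ctf-4 at V:10965626 to 10965780 had a signal of 99.997 (47.6 and 50.5). Those between rps-20 and ekl-4 (I:14469258 to 14469428) and between eef-1A.1 and rfc-4 (III:6972042 to 6972189) had signals of 95.8 and 93.6. W08E12.7 followed with 93.3, cox-5A, a subunit of cytochrome c oxidase, with 92.8 (III:12905101 to 12905268, 310 bp upstream), and rps-12 with 86.2. All of these summits lay outside the bodies of protein-coding genes, and those at the 4 gene pairs, like that of rps-12, which ska-3 shared, cannot be given to 1 gene.

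Several of the strongest regions lay around pha-4 itself (WBGene00004013, V:20753052 to 20760317, plus strand). The gene had 3 IDR regions in its promoter windows, the strongest with a signal of 60.8 and its summit 260 bp upstream, outside protein-coding genes (49.4 in replicate 1, 16.13 in replicate 2). The 2 strongest IDR regions of the genome, at V:20778224 to 20778622 (signal 226; 117 and 109) and V:20776762 to 20777087 (signal 155; 73.4 and 89.04), were intergenic. Their nearest annotated 5' ends were those of hif-1, a hypoxia-inducible factor, at 1986 bp and of F38A6.4 at 1524 bp. The third strongest region outside promoter windows was intergenic at X:11094129 to 11094313 (signal 126; 73.9 and 48.8), 3963 bp from the 5' end of W02H3.3. A run of regions with signal over 5 and gaps of at most 3000 bp, a definition chosen after the values were seen, reached from V:20744455 to V:20781114 (36.7 kb). It held 52 pooled and 14 IDR regions, against at most 45 and 8 in 2730 other windows of that length laid end to end along the chromosomes. The run's ends followed dense regions and those windows did not, so the counts do not show that no other stretch is as dense. The adjoining windows of the same length held 16 and 11 pooled regions, where the median window held 10. At unc-119 (III:10902641 to 10908935), the marker gene of the strain, there was no IDR region and 1 pooled region of signal 9.35, at rank 7563.

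**Figure D2:**
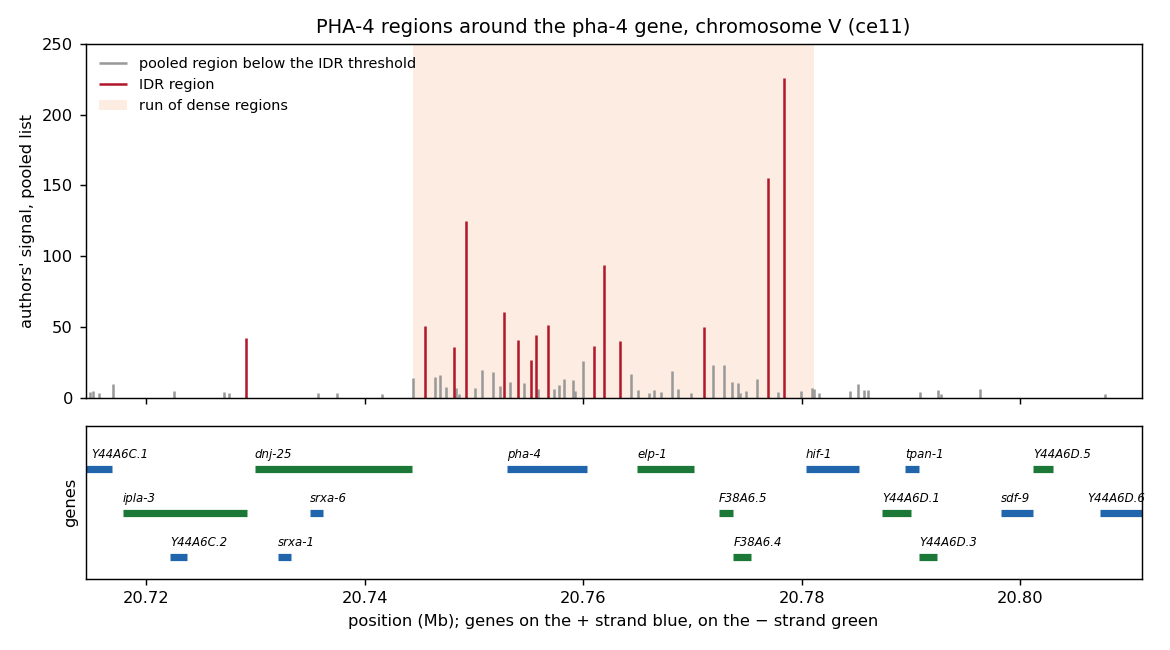
Authors' pooled signal (y axis, no unit) of each region by summit position on chromosome V in Mb (ce11), with IDR regions in red and weaker pooled regions in grey, above the protein-coding genes. The shaded run of 36.7 kb around pha-4 holds 52 pooled regions, 14 of them IDR regions, and the 2 highest lines stand upstream of hif-1.

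Most IDR regions lay in promoters of protein-coding genes. Their windows held 946 of 1484 summits, or 63.7% (61.2 to 66.2%), while they make up 26.2% of the genome (adjusted exact p = 3.04e-200, exact binomial test). Exons held 17 summits (1.15% against 21.5% of bases, adjusted exact p = 3.98e-126) and introns 121 (8.15% against 24.5%, adjusted exact p = 1.35e-59). Intergenic sequence held 254 (17.1% against 17.2%, adjusted exact p = 0.973) and promoters of non-coding RNA genes 146 (9.84% against 10.6%, adjusted exact p = 0.469). Neither of the last classes passed the test, except that both fell below their share with a window of 2000 and 500 bp (adjusted exact p = 0.0294 and 0.0239, with ranges over 6 alternatives of 0.0294 to 1 and 0.0239 to 0.803). The promoter regions tied 1246 of 19973 protein-coding genes to a region. Of the 946 regions, 304 (32.1%) lay in windows of more than 1 gene, and for 621 genes every region was shared with another gene.

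Ribosomal protein genes stood out among the 19 lists. Of 81 cytosolic ribosomal protein genes, 46 (56.8%, 45.3 to 67.8%) had an IDR summit in their window, against 7.74% of other named genes (Fisher's exact test, adjusted exact p = 1.30e-28). After rpl-20, rps-20 and rps-12, the strongest was rpl-12 with a signal of 82.9 (36.1 and 42.4), in a region shared with lin-54, while rla-0 and rla-1 had no region. In 33 of the 46 genes the region also lay in another gene's window. With each region given only to the nearest 5' end, 28 of the 81 genes (34.6%) had one, against 7.91% of others, and without the strongest 1 in 10 regions 27 (33.3%) had one, against 6.92%. Their adjusted exact p-values were 1.23e-10 and 3.55e-11 (range over 12 alternatives 3.93e-33 to 0.00475). The upper end of that range is an adjusted rotation p and not an exact p. Before adjustment it was 0.001, the smallest value that 1000 rotations can give, so it does not measure a weaker excess.

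Stress, autophagy and nutrient-signalling genes were also tied to regions more often than other genes. Of 46 antioxidant and stress response genes, 14 (30.4%, 17.7 to 45.8%) had a region, against 8.01% of others (adjusted exact p = 6.18e-05). They included the chaperone genes hsp-110 (73.9, in a window shared with the proteasome gene rpn-3) and hsp-90 (53.4, in its intron, shared with C47E8.4). Also among them were the co-chaperone gene dnj-13 (52.2, in an intron of dhgd-1, shared with F54D5.9) and wdr-23 (45.2), a negative regulator of the SKN-1 stress response. The catalase genes ctl-1 and ctl-2 had none. Of 40 autophagy and lysosome genes, 11 (27.5%, 14.6 to 43.9%) had a region, against 8.03% (adjusted exact p = 0.00114). The strongest were at the autophagosome protein genes lgg-2 (75.5; IV:10936024 to 10936333), epg-6 (65.7, in an intron) and lgg-1 (49.9), and at hlh-30 (42.8, in an intron), a TFEB-like regulator of autophagy, while atg-10 and atg-13 had none. Of 43 insulin, TOR and diet pathway genes, 9 (20.9%, 10.04 to 36.04%) had a region, against 8.05% (adjusted exact p = 0.0210). These included pha-4 itself, the kinase gene akt-2 (58.0), smk-1 (55.8, in an intron of smk-1 and a coding exon of fip-4) and the ubiquitin ligase gene wwp-1 (55.3), while aak-1 and aakb-1 had none. The call of this last list ended under 4 of 12 alternatives (adjusted exact p 0.000106 to 0.213), among them without replicate 1 (0.101) and without the run around pha-4 (0.0550).

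**Figure D3:**
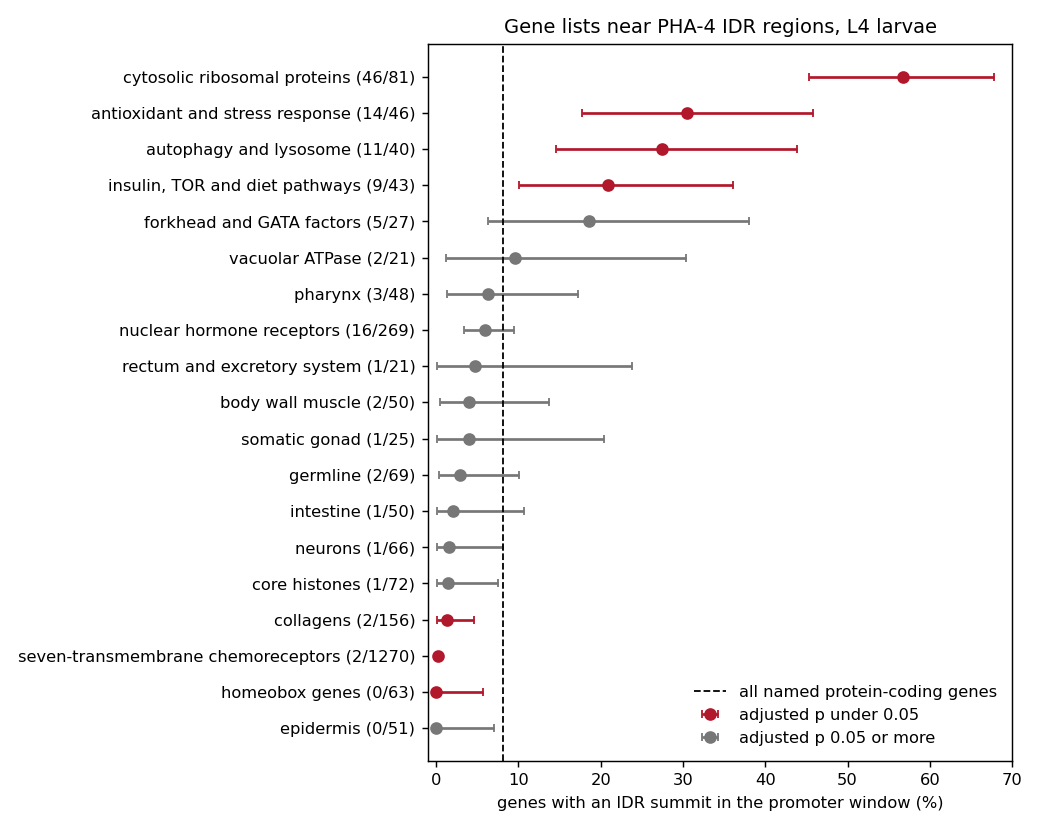
Percent of the genes of each list with an IDR summit in the promoter window (x axis) with exact 95% binomial intervals as bars, and counts in brackets. The list of ribosomal proteins lies highest at 56.8%, the dashed line marks the 8.10% of all named protein-coding genes, and red points passed the test at an adjusted p under 0.05.

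Genes of the organs in which PHA-4 acts did not stand detectably above other genes in the IDR list. The share in each of their lists was lower than in other genes. Of 48 pharynx genes, 3 (6.25%, 1.31 to 17.2%) had a region, against 8.11% of others (adjusted exact p = 1). These were pqn-71 (34.9, shared with rocf-1), peb-1, which encodes a pharyngeal DNA-binding protein (26.5, in its intron), and nhr-48 (26.3), while abu-1 and abu-10 had none. Leaving out replicate 2 gave 4 of 48 (8.33%) and leaving out replicate 1 gave 1 (2.08%), with adjusted exact p-values of 0.930 and 0.245. In the strongest 10000 pooled regions, a depth chosen after the data were seen, 20 of the 48 had one (41.7% against 31.7%, adjusted exact p = 0.235, range over 12 alternatives 0.235 to 1). The intestine list had 1 of 50 (2%, against 8.13% of others), at act-5, an intestinal actin gene (26.8). The rectum and excretory list had 1 of 21 (4.76% against 8.11%), at vha-8 (56.5, shared with C17H12.2). The somatic gonad list had 1 of 25 (4% against 8.11%), at fos-1 (32.1, in its 5' UTR). Adjusted exact p-values of these lists were 0.271, 1 and 0.802. Members without a region included the protease genes asp-1 and asp-3, aqp-8 and ceh-37, and apx-1 and cdh-3. With 21 to 50 genes a list, the intervals reached as high as 10.6%, 23.8% and 20.4%.

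Lists of other tissues likewise lay below the background in the IDR list, and with the main settings none passed the test. Body wall muscle had 2 of 50 (act-2, 40.8, and unc-52, 35.7, but not acr-16 or act-1; adjusted exact p = 0.549) and the germline 2 of 69 (nos-3, 43.3, and ima-2, 28.8, without a matched region in replicate 1, but not car-1 or cbd-1; 0.196). Neurons had 1 of 66 (ric-19, 31.9, but not ace-1 or ace-2; 0.0792) and the epidermis 0 of 51, which allows up to 6.98% (bli-1 and bli-2 among them; 0.0704). The regions of nos-3 and ric-19 lay in windows shared with Y53C12B.1 and pmlr-1. Some alternatives placed 3 of these lists past the threshold, all lower than other genes. In the strongest 6000 and 10000 pooled regions, depths chosen after the data were seen, adjusted exact p-values were 0.00212 and 0.000793 for neurons, 0.00333 and 0.000949 for the epidermis and 0.0292 and 0.00129 for the germline. Neurons also passed without replicate 1 (adjusted exact p = 0.0288) and the epidermis with the 2000 and 500 bp window (0.0204). Over 12 alternatives each, the adjusted exact p ran from 0.000793 to 0.349 for neurons, from 0.000949 to 0.328 for the epidermis and from 0.00129 to 0.916 for the germline. The vacuolar ATPase list had 2 of 21 (vha-8 and vha-15, 29.998, the latter without a matched region in replicate 2, but not unc-32 or vha-1; 0.802). Core histones had 1 of 72 (his-37, 78.6, but not his-1 or his-12; adjusted exact p = 0.0685), and passed as lower under 1 of 12 alternatives, without the strongest 1 in 10 regions (0 of 72, 0.0296, range 0.0296 to 0.548). Leaving out replicate 2 and replicate 1 in turn gave 3 and 2 of 72 core histone genes (adjusted exact p = 0.471 and 0.245), 1 and 4 of 69 germline genes, 2 and 0 of 66 neuron genes, 3 and 1 of 50 muscle genes and 3 and 1 of 21 vacuolar ATPase genes.

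The homeobox list had the size and counts of the ceh gene class, so it need not stand for homeobox genes with other names. It had 0 of 63 with a region, ceh-1 and ceh-10 among them, which allows up to 5.69% (adjusted exact p = 0.0244). In 6 of 12 alternatives that call ended (0.00343 to 0.249), among them rotation of the calls (adjusted rotation p = 0.0624) and leaving out replicate 1 (adjusted exact p = 0.172). Nuclear hormone receptor genes had 16 of 269 (5.95%, 0.290), the strongest at nhr-50 (47.9), nhr-112 (44.6), nhr-256 (43.2) and nhr-56 (41.7, in its 5' UTR), and none at nhr-10 or nhr-100. The nhr-256 region was listed with 36.8 in replicate 1 and 3.77 in replicate 2. Forkhead and GATA factor genes had 5 of 27 (18.5%, 6.30 to 38.1%; 0.108), namely pha-4, daf-16 (34.5), fkh-9 (34.3), fkh-7 (33.5) and, named after its value was seen, egl-27 (27.5), and none at egl-18 or elt-1. Chemoreceptor genes had 2 of 1270 (0.157%, against 9.15% of others, adjusted exact p = 4.73e-45), srh-89 (30.05, shared with F25E5.1) and srz-62 (27.9), and none at sra-1 or sra-10. Collagen genes had 2 of 156 (1.28%, against 8.20%, adjusted exact p = 0.00121), col-38 (46.5) and col-2 (42.1), and none at col-10 or col-101. Both collagen regions lay in windows shared with another gene, rpl-5 and ndc-80, and the collagen call ended with the stricter signal threshold (0.221, range over 12 alternatives 1.46e-14 to 0.221).

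Among 117 gene classes, 23 passed the test, 8 above and 15 below other named genes. Above stood rpl (29 of 47, adjusted exact p = 1.89e-18), rps (17 of 31, 1.26e-09), dnj (9 of 29, 0.00391), sec (7 of 19, 0.00504), cyn (6 of 16, 0.0107), hsp (7 of 22, 0.0116), lin (10 of 47, 0.0267) and cox (5 of 15, 0.0339). The sec class holds secretory pathway genes such as sec-61.G (85.8), sec-3 (50.2) and sec-16A.2 (37.8), and cyn holds cyclophilins, with cyn-1 (40.6), cyn-3 (40.3) and cyn-7 (31.7). The cytochrome c oxidase class had cox-5A, cox-6B (72.9) and cox-4 (42.7) with, named after their values were seen, cox-14 (35.98) and cox-5B (26.9), and the DnaJ co-chaperones dnj-9 (58.1), dnj-13 and dnj-11 (44.0). In rpl and rps, rpl-43 had 79.6 and rps-10 had 75.4. In hsp, hsp-16.2 (35.6) had 31.0 in replicate 1 and no matched region in replicate 2. The lin class is named after a mutant phenotype and not a shared protein, and lin-54 (82.9), lin-7 (56.6) and lin-53 (44.8) led it. Each of these regions lay in a window shared with another gene, such as rpl-12 at lin-54 and nra-2 at lin-53. The regions of sec-61.G, cyn-7, cox-6B, dnj-13, dnj-11, rpl-43 and rps-10 were shared too. Below stood the C-type lectin class clec (1 of 240, clec-126 with 29.5, adjusted exact p = 2.13e-06), 9 chemoreceptor classes such as str (0 of 193, 4.16e-06) and srh (1 of 220, 6.20e-06), the F-box classes fbxb (none, 0.00369) and fbxa (4 of 170, 0.0222), col, the neuropeptide class nlp (0 of 71, 0.0267) and ceh (0 of 63, 0.0457). The col and ceh classes had the same sizes and counts as the collagen and homeobox lists, so their calls are not separate results. Of the fbxa members, fbxa-76 and fbxa-77 shared a region of 39.99 and fbxa-90 had 30.7, in a window shared with efl-1. Rotating the calls along the gene order left 9 of the 23, namely rpl, rps, dnj, sec, cyn, hsp, clec, srh and col.

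The PHA-4 consensus was enriched at summits. TRTTKRY stood within 50 bp of 715 of 1484 summits (48.2%, 45.6 to 50.8%), against 27.02% of flanking windows (log2 ratio 0.83, adjusted exact p = 1.60e-31, exact binomial test). The narrower form TGTTTRY stood at 27.97% against 7.08%. The consensus was at 45.6% of summits in promoters and 52.8% outside them (Fisher's exact test, adjusted exact p = 0.0243). Its share did not differ detectably between the strongest 297 regions (48.5%) and the weakest 296 (46.6%; exact p = 0.681).

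Other sequences had steeper ratios. GAGAGA stood at 28.8% of summits against 5.19% of flanks (adjusted exact p = 8.57e-67) and CTGCGTC at 12.6% against 0.943% (3.70e-41). GAGAGA was rarer in promoters than outside them (24.8% against 35.9%, adjusted exact p = 4.63e-05), and CTGCGTC was rarer on X than on autosomes (6.67% against 14.1%, adjusted exact p = 0.00178). TRTTKRY stood in 34.2% of windows with CTGCGTC and 50.2% of those without (adjusted exact p = 6.57e-05), whereas GAGAGA stood in 51.3% and 25.6% (1.09e-11). The sequences GAGAGAC, AGAGACG, GAGACGC and GACGCAG, the last being CTGCGTC on the other strand, were all more frequent at summits. Joined by their overlaps they hold both GAGAGA and CTGCGTC. The shared windows may thus hold a single longer sequence and need not show separate sites that meet. The E-box CACGTG was at 4.65% against 2.22% (4.69e-04), the GATA site TGATAA at 4.85% against 8.96% (1.30e-05) and TTTTTT at 25.8% against 41.7% (3.45e-20). Summit windows held 44.2% G+C and flanks 35.6%. Against promoter windows of genes without a region matched to the same G+C, TRTTKRY kept its excess, with a higher ratio (22.2% of matched windows, log2 ratio 1.12, adjusted exact p = 1.25e-49, range over 9 alternatives 5.36e-50 to 8.52e-18). GAGAGA and CTGCGTC kept theirs with lower ratios. GAGAGA stood in 8.42% of matched windows (log2 ratio 1.78 in place of 2.47, adjusted exact p = 1.43e-47) and CTGCGTC in 1.55% (3.02 in place of 3.74, 6.15e-35), with ranges over 7 alternatives of 1.62e-85 to 8.78e-34 and 2.46e-52 to 2.16e-24. The calls of CACGTG (adjusted exact p = 0.0555) and TGATAA (0.223) ended, and TTTTTT turned to higher at summits (log2 ratio 0.25, adjusted exact p = 0.0164). Over 7 alternatives each, the adjusted exact p ran from 3.03e-06 to 0.0555 for CACGTG, from 6.41e-07 to 0.223 for TGATAA and from 1.47e-24 to 0.0164 for TTTTTT.

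**Figure D4:**
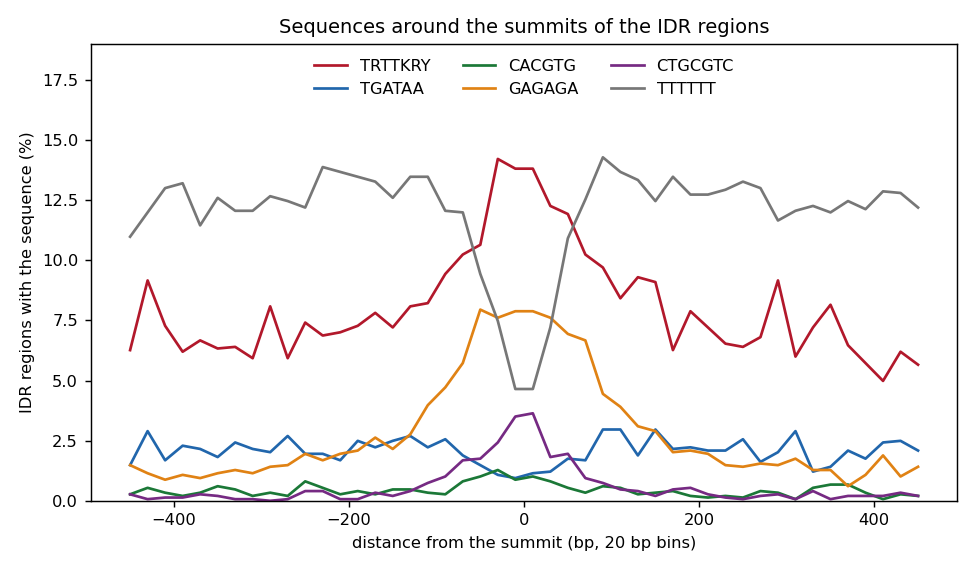
Percent of the 1484 IDR regions with each sequence on either strand (y axis) in 20 bp bins by distance from the summit in bp (x axis), 1 line per sequence. TRTTKRY, GAGAGA and CTGCGTC peak at the summit, while TTTTTT has a trough there.

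A search over all 8192 sequences of 7 bases found 744 more frequent and 660 less frequent at summits than in flanks. The first by p-value was AGAGACG (12.9% against 0.741%, adjusted exact p = 4.59e-41), followed by AGACGCA, GAGACGC and CTGCGTC, which overlap one another, and by CTCTCTC (13.9% against 1.35%). Of the 16 sequences of the PHA-4 consensus, 7 were more frequent at summits and 0 less frequent. The first of them, TGTTTAC, ranked 13 among the more frequent ones (8.56% against 0.943%, adjusted exact p = 8.11e-22). AAAAATT led the less frequent ones (7.14% against 26.01%, adjusted exact p = 1.71e-40). With the background matched on G+C, 723 sequences passed in place of 1404, and 308 of the 744 still passed as more frequent. Leaving out the run around pha-4 kept 601 of the 744. That setting also drew the side of the flanks anew for other regions, so its losses need not come from the run. The loss with matched G+C likewise need not come from G+C alone.

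Regions were unevenly spread over the chromosomes. Chromosome X held 300 summits (20.2%, against 14.7% expected from promoter windows, adjusted exact p = 2.93e-08) and III held 262 (17.7% against 12.8%, 1.43e-07). Chromosome V held 219 (14.8% against 24.1%, 5.32e-18) and IV 220 (14.8% against 17.2%, 0.0200). Chromosomes I (242, 0.0505) and II (241, 0.602) did not pass. Among promoter regions only, a setting added after the data were seen, X held 16.7% and no longer passed (adjusted exact p = 0.107, range over 7 alternatives 8.31e-09 to 0.107), nor did IV (0.0873, range 0.00778 to 0.0873), while I passed (0.0248, range 0.0102 to 0.715). Promoter windows of protein-coding genes held 52.7% of the regions on X and 63.01 to 71.8% of those on the autosomes.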

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

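The tests of this part, except that of sequences made of the same bases, were chosen after the result was seen. Regions at middle ranks of the pooled list, below the IDR threshold and not used in the comparisons of motifs, were enriched for a GATA site that was not enriched in the IDR list. TGATAA stood at 16.6% of summits at ranks over 3000 up to 6000 (9.97% of flanks, adjusted exact p = 9.04e-14) and at 14.8% at ranks over 6000 up to 10000 (8.97%, 8.65e-16), against 4.85% in the IDR list. At ranks 1485 to 3000 it stood at 9.96% of summits and 9.17% of flanks (adjusted exact p = 0.488), and at ranks over 10000 at 10.99% and 9.195% (log2 ratio 0.26, 2.95e-09), a smaller excess. Over the same ranks TRTTKRY went from 48.2% in the IDR list to 44.3% at ranks over 3000 up to 6000 and 28.5% at ranks over 10000, and CTGCGTC from 12.6% to 6.30% and 1.53%.

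Base composition of the weaker regions as the source was argued against by the other 6-base sequences with the same bases. At ranks over 3000 up to 6000, the ratio of TGATAA between summits and flanks was 1.66, the highest of 60 such sequences, of which the next had 1.09 and the median of the others was 0.644. GATA factors regulate genes of the intestine, so a candidate explanation is that the weaker regions include intestinal ones. Genes of the intestine list had a region of ranks over 3000 up to 10000 in 14 of 50 cases (28%, 16.23 to 42.5%) against 19.8% of other named genes. Fisher's exact p was 0.155, and 0.248 when adjusted over the tissue lists, which leaves that open. Binding by another factor at the same sites was not tested.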

How the results depend on the processing

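Deeper pooled lists, the list without the run around pha-4 and promoter regions only were chosen after the data were seen. The promoter share and TRTTKRY kept their direction and side of the threshold under all 6 and 9 alternatives (log2 ratios 0.70 to 1.92 and 0.55 to 1.98), as did the lists of ribosomal proteins, stress, autophagy and chemoreceptors under all 12. The replicate overlap was 46.2% for summits within 100 bp, 45.1% with 742 regions and 55.8% with double the number; 742 IDR regions reached the median signal. Gene classes past the threshold numbered 6 at that signal, 14 with the 500 and 100 bp window and 9 with rotation (16 to 18 with 1 replicate), and sequences at summits 903 for 6 bases and 723 with matched G+C. With the 2000 and 500 bp window 24 gene classes passed, of which 19 were among the 23 of the main setting. Against all protein-coding genes 18 gene classes passed, of which 15 were among those 23. The shorter lists, fewer sequences and smaller window by construction hold fewer items; otherwise the cause was not tested. TTTTTT, lower at summits than in flanks and past the threshold, turned to higher and past it with matched G+C (log2 ratio 0.25), a background richer in G+C than flanks. Of results off the threshold, these log2 ratios turned. With the 500 and 100 bp window, non-coding promoters had 0.21, intergenic sequence 0.057 and the rectum list 0.018, and with 2000 and 500 bp the rectum list 0.15. At the median signal, rectum had 0.67, muscle 0.19, chromosome I −0.055 and II 0.074. Without the strongest regions, pharynx had 0.0045 and vacuolar ATPase −0.063. By nearest 5' end, pharynx had 0.18, gonad 0.24, muscle 0.12, vacuolar ATPase −0.25 and nuclear receptors 0.39. Against all protein-coding genes, pharynx had 0.19 and rectum 0.13. With 1 replicate left out, pharynx ran from −1.34 to 0.27, vacuolar ATPase from −0.18 to 1.07 and chromosome II from −0.058 to 0.035. In the strongest 6000 pooled regions, pharynx had 0.094, intestine 0.036, muscle 0.15 and nuclear receptors 0.066, and in the strongest 10000, 0.40, 0.11, 0.20 and 0.15, with gonad at 0.044. Chromosome II had 0.092 by share of bases and 0.13 in promoters. The ce10 list held 1737 regions. Depth is unknown from these lists.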

Other observations

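The gene groups, ranks and tests of this part were chosen after the IDR list was seen, with 2 exceptions at ribosomal protein genes. The test of promoter G+C and the comparison of TRTTKRY with promoter windows matched on G+C were fixed before their results. Counts are given without tests for 8 groups of growth and energy genes, since the groups were picked after genes in them, such as eef-1G, eef-1A.1 and the cox genes, had been seen. An IDR region stood at 5 of 6 translation elongation factor genes (eef-1G, eef-1A.1, eef-2, eef-1A.2 and eef-1B.2), 13 of 44 genes of the respiratory chain and ATP synthase, 8 of 33 proteasome genes, 3 of 8 cytosolic chaperonin genes (cct-6, cct-1 and cct-8) and 12 of 70 mitochondrial ribosomal protein genes. It stood at 2 of 32 aminoacyl-tRNA synthetase genes (fars-1 and kars-1), 4 of 25 initiation factor genes (eif-3.B, eif-3.J, eif-2beta and eif-3.E) and 2 of 7 Sm protein genes (snr-3 and snr-6). Among the strongest were rpn-9 (77.9), rpn-3 (73.9), cox-6B and nduc-2 sharing 72.9, and atp-3 (53.4).

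At ranks over 3000 up to 10000 of the pooled list, 17 of 48 pharynx genes had a region (35.4%, 22.2 to 50.5%) against 19.8% of other named genes (Fisher's exact test over 8 tissue lists, adjusted exact p = 0.0415). Epidermis genes lay below the others at these ranks (3 of 51, adjusted exact p = 0.0415), and neurons (6 of 66, 0.0579) and germline (6 of 69, 0.0579) did not pass. Over all of the strongest 6000 and 10000 regions, tested with the 19 lists, pharynx did not pass (12 of 48 and 20 of 48, adjusted exact p = 0.914 and 0.235, range over 12 alternatives 0.235 to 1). Among non-coding genes, 33 of 346 snoRNA genes (9.54%) had an IDR summit in their window, 24 of 612 tRNA genes (3.92%) and 123 of 15363 piRNA genes (0.801%).

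The regions of ribosomal protein genes differed in sequence from the rest. Of 43 such regions, 8 (18.6%, 8.39 to 33.4%) had TRTTKRY at the summit, against 49.1% of the other IDR regions (adjusted exact p = 2.10e-04). Against the 903 other IDR regions in protein-coding promoters TRTTKRY was rarer too (46.8% of those, Fisher's exact p = 2.36e-04). GAGAGA (9.30% against 29.4% of all other IDR regions, adjusted exact p = 0.00473) and CTGCGTC (1 region, 2.33% against 12.9%, 0.0348) were also rarer, so the lack was not shown to be specific to the PHA-4 consensus. These sequences were not compared within promoters, and GAGAGA was rarer in promoters in general (24.8% against 35.9% outside). In the comparison fixed beforehand, promoter windows matched on the G+C of all IDR summits, and not of these 43, had TRTTKRY in 22.2%. Promoter G+C as the source was argued against, since genes of the same promoter G+C would give 9.29% with a region where 56.8% (45.3 to 67.8%) had one. Windows shared with a neighbour were argued against as the whole source, since 16.05% of ribosomal protein genes and 4.03% of others had a region in their window alone (Fisher's exact p = 2.41e-05). The control and other factors were not analysed here, so binding through other proteins and signal common to active promoters both stay open.

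The dense run around pha-4 may come from extra copies of the tagged locus in the strain or from PHA-4 bound in and around its own gene. Only 4 of its 14 IDR regions lay within pha-4, and the 2 strongest lay beyond elp-1 and F38A6.4. If extra copies raised signal regardless of binding, the motif should be rarer in the run. TRTTKRY stood at the summit of 7 of its 14 IDR regions (50%, 23.04 to 77.0%) against 48.2% of the others (Fisher's exact p = 1). Extra copies would raise bound sites with the motif as well, so its share cannot tell the explanations apart, and 14 regions are few. The median pooled signal was 12.5 in the run and 5.07 elsewhere, but the run was defined by regions with signal over 5.

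Regions strong in 1 replicate alone were compared between the replicates. Of each replicate's strongest 1484, 740 did not overlap the other's, and 59.7% of those in replicate 1 and 60.3% in replicate 2 lay in protein-coding promoters (Fisher's exact test, adjusted exact p = 0.955). TRTTKRY stood at 45% and 48.4% of them (0.739) and GAGAGA at 29.3% and 23.8% (0.129), and TGATAA at 8.11% and 9.19% (0.906). None of the 7 comparisons between the replicates passed, which does not show that the regions were alike. The 744 shared regions, with TRTTKRY at 46.9% and TGATAA at 4.17%, were not tested against them. Genes with a region strong in replicate 1 alone and in replicate 2 alone were counted in each of the 19 lists and not tested. They numbered 8 and 9 in ribosomal proteins, 12 and 8 in nuclear hormone receptors, 4 and 3 in stress response, 4 and 2 in insulin, TOR and diet pathways, 1 and 4 in autophagy, 3 and 0 in pharynx, 0 and 3 in germline and 1 and 1 in intestine. Each of the other 11 lists had at most 2 from either replicate alone.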
